A study of Mus musculus with 6 samples.

How the data were processed

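RNA was sequenced from primary mouse Sertoli cells, the somatic cells of the seminiferous tubule that support germ cells. Per the labels, the cells came from C57BL/6 mice and were enriched by differential plating. The 3 wild-type libraries came from cells infected with an empty plasmid. The 3 UXT knockout libraries came from cells of knockout animals infected with a viral construct carrying Cre recombinase. UXT, also called ART-27, is a small prefoldin-like protein encoded on the X chromosome. Per the labels' protocols, libraries were made with a stranded kit for messenger RNA. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate animals or cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

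FastQC, STAR, DESeq2 and the mm10 genome build were named, without versions, per the submitters' processing notes. The aligner settings, the read counter, the gene annotation and the use of strand in counting were not given in the sources used here. The authors deposited a single table, in which each of the 3257 genes analysed had a fold of at least 1.5 and an adjusted p-value under 0.05 (the largest was 0.0499) on these same libraries. Per the file headers, it held a signed fold change, a log fold change, a p-value, an adjusted p-value and the average log2 expression of each gene, with a value per library. The signed fold score deposited by the authors was the knockout over wild-type ratio for higher genes, and minus the inverse ratio for lower genes. The deposited log2 fold change was the log2 of that ratio. The deposited p-values and adjusted p-values were those of the authors' test, and 56 adjusted p-values in the authors' deposited table were listed as 0. The deposited values per library were on a log2 scale, normalized between libraries by the authors with a transformation not given in the sources used here.

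The values per library were moderated. With the genes in 4 groups by expression, the difference between group means was, in the lowest group, 0.24 of the log2 fold change in the authors' deposited table (median ratio). In the highest group it was 0.65 of the log2 fold change in the authors' deposited table. Fold sizes below are therefore the authors', and the values per library served for the spread, the test and the direction. No counts were used, so the depth of each library was unknown and no counting interval or detection floor was computed. The table had 3261 rows. The symbols Efna1 and Hmga1 each stood on 2 rows with different values, so 4 rows were left out and 3257 genes were analysed.

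Genes were tested with limma 3.58.1 in R 4.3.3 with a mean-variance trend, on the deposited log2 values of all 6 libraries, with no covariate. The design had assumed linear values and a pseudocount, which were not needed for values already on a log2 scale. P-values were adjusted by the Benjamini-Hochberg method over the 3257 genes. A gene was called higher or lower at an adjusted p under 0.05 and a fold of at least 1.5 in the authors' deposited table. Because the table was selected on these libraries, limma's calls are not independent evidence that a gene differs. Genes outside the table were not analysed here and cannot be called unchanged.

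The lists of genes were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives not said to be added. The 30 lists covered Sertoli identity, cell junctions, extracellular matrix, integrins, actin, tubulins, prefoldin and chaperonin, androgen targets, p53 targets, interferon, NF-kB and cell cycle genes. They also covered cholesterol, fatty acid metabolism, glycolysis, the integrated stress response, heat shock, NRF2 targets, TGF-beta and YAP genes, the respiratory chain, ribosomal proteins, lysosomes and chromatin repressors. Marker lists were included for Leydig, myoid, fibroblast, macrophage, endothelial, germ and red blood cells. A selected table has no background of unselected genes. Each list with at least 5 called members was therefore tested for its balance of higher and lower genes, against the other called genes, with a two-sided Fisher's exact test. P-values were adjusted over the 25 lists tested. The set tests camera, with a preset and with an estimated correlation between genes, and fry were run on the same lists. The level of a list in a library was the median, over its members, of the deviation from the wild-type mean. Such levels were compared by a two-sided exact permutation test, which cannot give a p under 0.1 for 3 libraries against 3.

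Named genes had separate groups, that is, all 3 knockout values above or all below the 3 wild-type values, and a mean normalized value of at least 50. They were the 4 genes with the largest rise and the 4 with the largest fall. The 3 higher and 3 lower genes with the smallest adjusted p not yet named followed. For each list with at least 3 called members they were its 2 members with the largest fold, or 3 for a list with a called direction. Gene models without a standard symbol were skipped, and an item that the rule would name is not reported here. Wt1, Sox9, Dhh, Mro, Dsp, Hspg2, Gstm2, Gstm3, Gstm6, Mgst1, Cox7a1, Alas2, Snhg7, Snhg1, Gas5, Lyz2 and Cdh5 lie outside this rule and were chosen after their values were seen.

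The limma step was tested on simulated data with the 3257 genes and this comparison. It recovered 10% of 50 genes changed by 0.25 on the log2 scale, 86% at 0.5, 96% at 1 and 100% at 2. Of 3057 unchanged simulated genes, 5 were called. In the real data 3244 of the 3257 genes passed, so the adjustment of p-values was stricter in the simulation. The recovered shares therefore do not carry over to the real data. Of simulated lists without a direction, 3.6% had a p under 0.05 in Fisher's exact test. Their genes were drawn at random, so that share does not cover lists with correlated members. Coordinates were taken from RefSeq for the GRCm38 assembly, which is the same assembly as mm10. Of the 3259 symbols, 3250 matched a RefSeq gene by gene identifier and 3169 matched a GENCODE transcript, which gave length and GC content.

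The alternatives were quantile normalization between libraries, a minimum mean of 50, an adjusted p of 0.01, a fold of 2, no fold threshold, the replicate number as a block, each library left out in turn and the authors' own calls. For lists, they were the 2 other set tests and the removal of genes that another list held. Uxt was not analysed here, so the labels were not checked against the level of the targeted gene.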

Results

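Gene expression was compared between primary Sertoli cells of wild-type mice and cells of UXT knockout mice, with 3 libraries in each group. The question was which transcripts differ when UXT, a prefoldin-like cofactor that binds the androgen receptor, is lost from these cells. The authors' deposited table held 3257 usable genes, each selected beforehand at a fold of at least 1.5 on these libraries. The depth of the libraries was unknown. The median log2 value over the table's genes lay between 9.15 and 9.18 in the wild-type libraries and between 8.82 and 8.91 in the knockout libraries. The median SD between replicates was 0.0931 in wild-type cells and 0.102 in knockout cells (n = 3 each), on the log2 scale. Only knockout cells had received Cre, so the loss of UXT could not be separated from the viral construct that carried Cre in any comparison.

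Knockout cells had lower levels of transcripts for Sertoli cell products, cell junctions, extracellular matrix and interferon-induced proteins, and higher levels of transcripts for heat shock proteins, chaperonin subunits and NRF2 targets. By Fisher's exact test 16 of 25 lists leaned one way, each with an adjusted p = 0.524 with an estimated correlation. Markers of endothelial cells and macrophages fell the most among the 25 lists tested, by medians of 9.52-fold and 5.17-fold in the authors' deposited table. Heat shock genes were higher in the knockout by a median of 1.90-fold in the authors' deposited table. Falls were larger than rises, with a median fold of 2.33 among lower genes and 1.75 among higher genes in the authors' deposited table. This comparison depends on the scaling between libraries. Quantile normalization raised the median difference of the moderated values by 0.26 on the log2 scale.

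Of the 3257 genes, 1044 were called higher and 2200 lower in the knockout by limma, so that 67.8% of the called genes were lower. The authors' deposited table listed 1047 as higher and 2210 as lower. After quantile normalization between libraries, which raised the median difference by 0.26 on the log2 scale, 1049 genes were higher and 1143 lower, a share of 52.1% lower. In 3175 genes (97.5%) the 3 knockout values all lay above or all below the 3 wild-type values. The share of 10% by chance for unselected genes does not apply, since these genes were selected on these libraries. The first principal component of the 6 libraries held 90.5% of the variance, which the same selection favours. A fold of at least 4 in the authors' deposited table was reached by 25 higher and 440 lower genes.

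**Figure D1:**
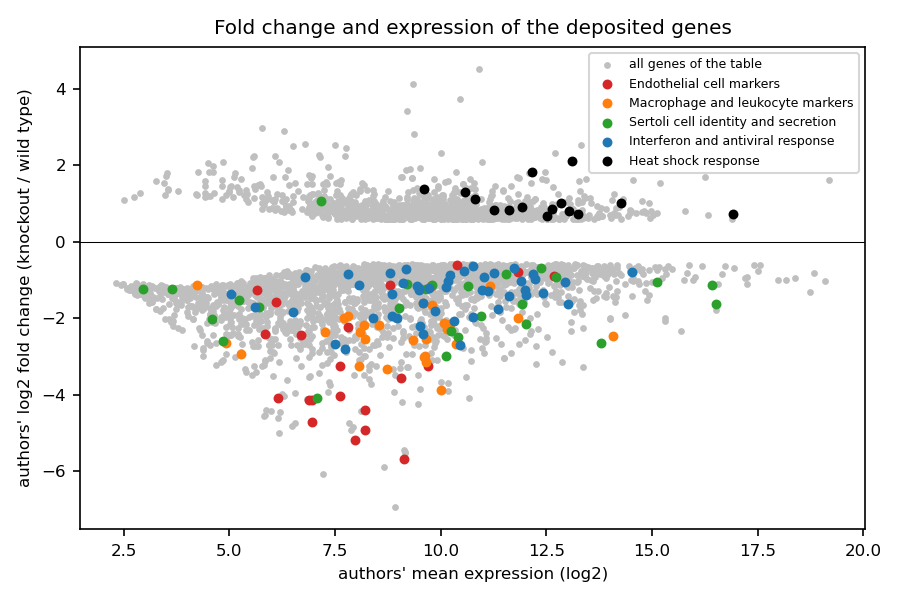
Each point is a gene of the authors' deposited table, with its mean log2 expression on the x axis and its log2 fold change (knockout over wild type) on the y axis. Endothelial markers (red), with a median of -3.25, and macrophage markers (orange), with a median of -2.37, lie below 0, and heat shock genes (black), with a median of 0.92, lie above 0.

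The largest rise was that of Grem1, a secreted antagonist of bone morphogenetic proteins, at 23.1-fold in the authors' deposited table. Grem1 (gene ID 23892, chromosome 2, 113748675 to 113758648 in GRCm38) had a mean log2 value of 8.05 ± 0.23 (SD, n = 3) in wild-type and 11.15 ± 0.12 (SD, n = 3) in knockout cells. Its limma difference was 3.10 ± 0.12 (SE, adjusted p = 8.65e-07). Akr1c18, a steroid dehydrogenase that inactivates progesterone, rose 17.5-fold, Vsig8 rose 13.4-fold and Robo2, a guidance receptor, rose 10.7-fold in the authors' deposited table. The largest fall was that of Dll4, a Notch ligand, at 124-fold in the authors' deposited table. Dll4 (gene ID 54485, chromosome 2, 119325784 to 119335666 in GRCm38) went from 9.03 ± 0.10 to 6.22 ± 0.07 (SD, n = 3 each), a limma difference of -2.82 ± 0.10 (SE, adjusted p = 4.55e-07). Gpihbp1, which anchors lipoprotein lipase to capillary endothelium, fell 68.2-fold, the receptor phosphatase Ptprv 60.0-fold and von Willebrand factor Vwf 51.8-fold in the authors' deposited table.

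Among the remaining genes with the smallest adjusted p, Hsph1, a heat shock protein, rose 4.36-fold, the chromatin protein Hmga2 rose 7.13-fold and the non-coding RNA Zfas1 rose 4.29-fold in the authors' deposited table. Zfas1 lies antisense to a neighbouring gene, so its value is uncertain where reads were counted without strand. The chemokine Ccl20 fell 43.4-fold, Myoz2 14.9-fold and Unc13d 14.5-fold in the authors' deposited table.

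Transcripts of Sertoli cell identity and secretion fell. Of 50 fixed genes, 26 were in the table, and 25 fell and 1 rose, with 26 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.00306, and adjusted p = 0.524 with an estimated correlation). Shbg, which encodes androgen-binding protein, fell 17.2-fold, the cystatin gene Cst12 7.94-fold and the transferrin gene Trf 6.33-fold in the authors' deposited table. Trf, the most abundant of the 3, went from 14.18 ± 0.11 to 12.42 ± 0.15 (SD, n = 3 each; limma adjusted p = 2.80e-06). Chosen after their values were seen, the transcription factor genes Wt1 and Sox9 fell 4.47-fold and 1.81-fold, and Dhh, a Sertoli cell ligand, fell 5.67-fold in the authors' deposited table. The gene that rose was Mro, at 2.09-fold in the authors' deposited table. The list's level was 0.00 ± 0.13 in wild-type and -0.80 ± 0.17 in knockout cells (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). In the same libraries the level of macrophage markers was -1.32 ± 0.11 and that of endothelial markers -1.15 ± 0.09 in knockout cells (SD, n = 3). Sizes of levels, here and below, cannot be compared between lists, since the values per library were moderated to an extent that varied with expression.

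Of 50 genes for the blood-testis barrier and cell junctions, 23 were in the table, and 20 fell, 2 rose and 1 (Dsp, limma adjusted p = 0.0677) did not pass. The count was 22 adjusted over the list alone, and the balance passed (Fisher's exact test, adjusted p = 0.0324, and adjusted p = 0.524 with an estimated correlation). Cldn5 fell 26.5-fold, Esam 21.1-fold and the tight junction gene Cgn 11.7-fold in the authors' deposited table. Cldn5 and Esam were also on the endothelial list. Without the members that a cell type list held, an alternative added after seeing the data, the adjusted p of the junction list was 0.0861, and without genes that any other list held it was 0.258. Of 35 androgen receptor targets, 9 were in the table, with 3 higher and 6 lower and 9 called adjusted over the list alone, and the balance did not pass (Fisher's exact test, adjusted p = 1). Gpd1 fell 6.56-fold and the homeobox gene Rhox5 3.25-fold in the authors' deposited table, and Rhox5 no longer passed after quantile normalization (difference -0.07).

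Genes of the extracellular matrix fell, with 31 lower and 1 higher of the 32 in the table, out of 62 fixed, and 32 called adjusted over the list alone (Fisher's exact test, adjusted p = 5.21e-04, and adjusted p = 0.524 with an estimated correlation). The cross-linking enzyme gene Loxl2 fell 4.19-fold, the collagen gene Col11a1 3.45-fold and the tenascin gene Tnxb 3.25-fold in the authors' deposited table. Loxl2 went from 15.67 ± 0.13 to 14.24 ± 0.28 (SD, n = 3 each; limma adjusted p = 3.76e-05). The gene that rose was Hspg2, which encodes perlecan, at 1.63-fold in the authors' deposited table. All 13 integrin and focal adhesion genes in the table, of 43 fixed, fell, with 13 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.0234, and adjusted p = 0.524 with an estimated correlation). Itga7 fell 7.52-fold, Itgb3 3.52-fold and Itga1 3.32-fold in the authors' deposited table. Interstitial fibroblast markers, 7 of whose called genes other lists also held, stood at a level of -0.85 ± 0.32 in the same knockout libraries (SD, n = 3).

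All 11 actin cytoskeleton genes in the table, of 48 fixed, fell, with 11 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.0324, and adjusted p = 0.524 with an estimated correlation). Ezr, which encodes ezrin, fell 7.43-fold, Lcp1, a plastin of leukocytes, 6.82-fold and Fhod3 5.17-fold in the authors' deposited table. The level of the actin list was -0.84 ± 0.13 in knockout cells (SD, n = 3), beside -0.75 ± 0.20 for myoid markers. Without the members that a cell type list held, the adjusted p of the actin list was 0.249, without genes that any other list held it was 0.258, and with genes called at an adjusted p of 0.01 it was 0.0545. Of 36 tubulin and microtubule genes, 6 were in the table, with 2 higher and 4 lower and 6 called adjusted over the list alone (Fisher's exact test, adjusted p = 1). Map2 fell 3.27-fold and Tubb4a 2.81-fold in the authors' deposited table. Of 41 TGF-beta, YAP and mesenchymal genes, 19 were in the table, with 3 higher and 16 lower and 19 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.202). With genes called at an adjusted p of 0.01, the balance of this list passed (Fisher's exact test, adjusted p = 0.0323). The set test fry, which does not compare a list with other genes, also called it (adjusted p = 5.17e-04). Its mean limma difference was -0.60. The genes of this list had been selected on these libraries, which favours a call by fry. Bmp2 fell 6.95-fold and the tissue factor gene F3 5.63-fold in the authors' deposited table.

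Heat shock genes rose, with all 15 in the table higher, of 23 fixed, and 15 called adjusted over the list alone (Fisher's exact test, adjusted p = 4.80e-07, and adjusted p = 0.524 with an estimated correlation). Hsph1 went from 12.08 ± 0.09 to 13.48 ± 0.17 (SD, n = 3 each), a limma difference of 1.39 ± 0.10 (SE, adjusted p = 7.48e-06). Hspa1b rose 3.54-fold and Hspa1a 2.61-fold in the authors' deposited table, and since these genes are near-identical copies their separate values are uncertain. Of 22 genes of the prefoldin, URI and chaperonin complexes, 9 were in the table, with 8 higher and 1 lower and 9 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.0026, and adjusted p = 0.524 with an estimated correlation). The chaperonin subunit genes Cct3 and Cct7 rose 1.85-fold and 1.64-fold in the authors' deposited table. The prefoldin subunit gene Vbp1 fell 2.76-fold in the authors' deposited table. The wild-type libraries differed widely in Vbp1 (9.82 ± 0.63, against 8.79 ± 0.15 in the knockout; SD, n = 3 each; limma adjusted p = 0.00426).

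Of 40 NRF2 targets and glutathione genes, 18 were in the table, with 13 higher and 5 lower and 18 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.00235, and adjusted p = 0.524 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose 3.49-fold and Srxn1 3.13-fold, while the glutathione transferase gene Gsta4 fell 3.59-fold in the authors' deposited table. The other genes of this list that fell, Gstm2, Gstm3, Gstm6 and Mgst1, also encode glutathione transferases and were named after their values were seen. The 6 ribosomal protein genes in the table, of 40 fixed, all rose, with 6 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.00306, and adjusted p = 0.524 with an estimated correlation). Rps12 rose 1.81-fold, Rpl27 1.72-fold and Rplp0 1.69-fold in the authors' deposited table. Ribosomal protein genes have many near-identical pseudogenes, so these values are uncertain. With genes called at an adjusted p of 0.01, fewer than 5 ribosomal protein genes were left and the list was not tested. Of 42 genes of the integrated stress and unfolded protein response, 9 were in the table, with 4 higher and 5 lower and 9 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.573). The median of this list was -0.61 on the log2 scale in the authors' deposited table. Its mean limma difference was 0.03, of the other sign. The transporter gene Slc7a11 rose 2.65-fold and Vldlr fell 2.67-fold in the authors' deposited table. Of 38 p53 targets, 10 were in the table, with 6 higher and 4 lower and 10 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.126). The median of the p53 list was 0.64 in the authors' deposited table. Its mean limma difference was -0.12. Gdf15 fell 6.72-fold and Perp 2.58-fold in the authors' deposited table, and Perp no longer passed after quantile normalization (difference -0.19).

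Interferon and antiviral genes fell, with all 47 in the table lower, of 61 fixed, and 47 called adjusted over the list alone (Fisher's exact test, adjusted p = 3.17e-07, and adjusted p = 0.524 with an estimated correlation). The guanylate-binding protein gene Gbp5 fell 6.95-fold, Ifit3 6.56-fold and Mx2 6.43-fold in the authors' deposited table. Ifit3 went from 10.81 ± 0.05 to 9.04 ± 0.34 (SD, n = 3 each; limma adjusted p = 1.67e-05). The list's level was -0.77 ± 0.22 in knockout cells (SD, n = 3), beside -1.32 ± 0.11 for macrophage markers. Of 46 NF-kB targets and inflammatory genes, 23 were in the table, with 2 higher and 21 lower and 23 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.0234, and adjusted p = 0.524 with an estimated correlation). Without wild-type replicate 1 the adjusted p of this list was 0.05. Besides Ccl20, the lipocalin gene Lcn2 fell 9.64-fold and the chemokine gene Cxcl2 4.85-fold in the authors' deposited table.

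**Figure D2:**
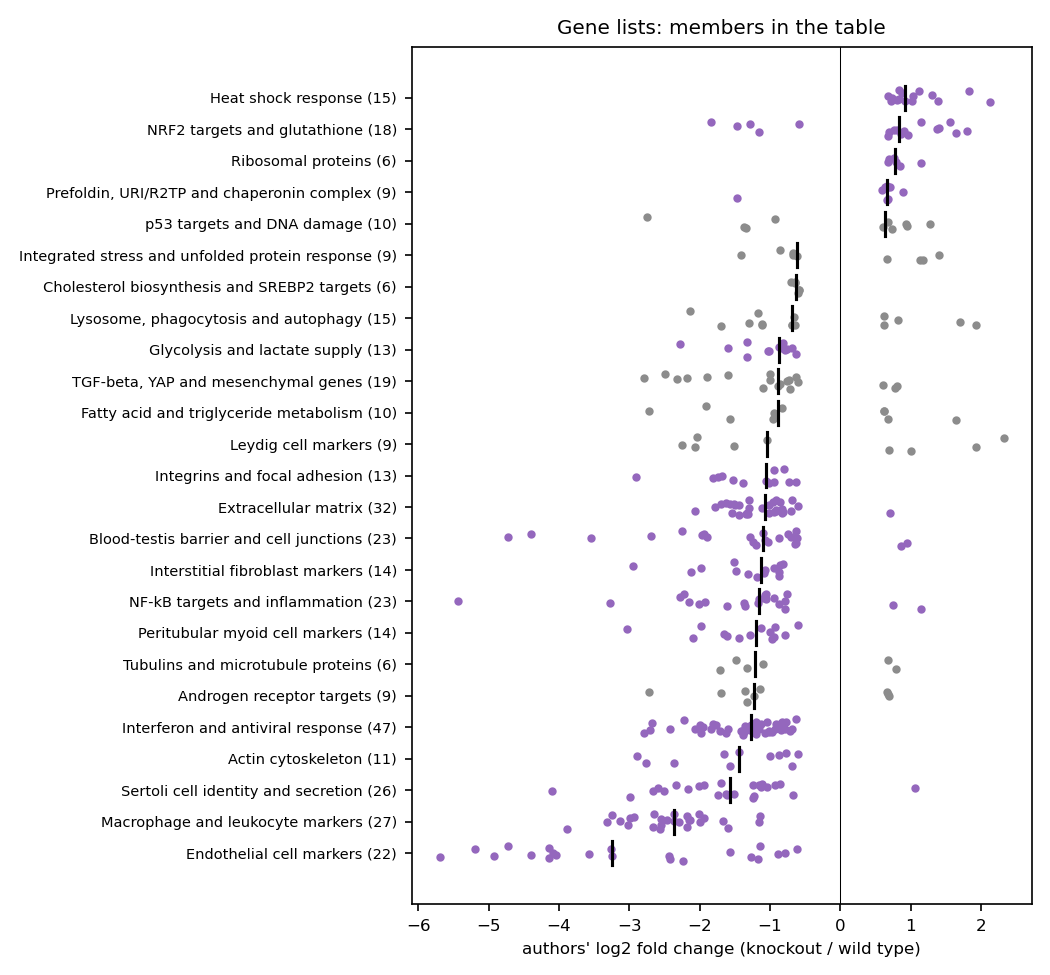
Points are the members of each list that were in the authors' deposited table (number in brackets), by log2 fold change of knockout over wild type, and black bars are medians. Purple lists have a called direction and grey lists do not. The medians run from -3.25 for endothelial markers to 0.92 for heat shock genes.

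All 13 genes of glycolysis and lactate supply in the table, of 25 fixed, fell, with 13 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.0234, and adjusted p = 0.524 with an estimated correlation). The lactate dehydrogenase gene Ldhb fell 4.85-fold, the aldolase gene Aldoc 3.03-fold and Pdk1 2.50-fold in the authors' deposited table. The supply of lactate was not measured. The level of the glycolysis list was -0.57 ± 0.12 in knockout cells (SD, n = 3), beside -1.32 ± 0.11 for macrophage and -1.15 ± 0.09 for endothelial markers. Of 43 fatty acid and triglyceride genes, 10 were in the table, with 4 higher and 6 lower and 10 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.836). Lpl, the lipoprotein lipase gene, fell 6.62-fold and the fatty acid transporter gene Cd36 3.74-fold in the authors' deposited table. The 6 cholesterol synthesis genes in the table, of 25 fixed, were lower, with 6 called adjusted over the list alone, and the balance did not pass (Fisher's exact test, adjusted p = 0.245). Tm7sf2 fell 1.62-fold in the authors' deposited table, and the limma difference of Tm7sf2 turned from -0.37 to 0.05 after quantile normalization. Of 39 lysosome and autophagy genes, 15 were in the table, with 5 higher and 10 lower and 15 called adjusted over the list alone (Fisher's exact test, adjusted p = 1). The cathepsin gene Ctss, also a macrophage marker, fell 4.39-fold and the engulfment receptor gene Megf10 rose 3.80-fold in the authors' deposited table. Camera placed the androgen, fatty acid, stress response, lysosome and Leydig lists on the higher side of the table's genes, although their median fold changes were negative. No camera test of these lists passed, with adjusted p from 0.651 to 0.943 at the preset correlation. Fry, which does not compare a list with other genes, called the androgen, fatty acid, lysosome and Leydig lists (largest adjusted p = 0.0216). It did not call the stress response list (adjusted p = 0.0806). The mean limma differences of the lists that fry called here were negative (-0.34, -0.34, -0.22 and -0.15, in that order). All members had been selected on these libraries, which favours a call by fry.

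Markers of other testis cells also differed. All 22 endothelial markers in the table, of 27 fixed, fell, with 22 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.00148, and adjusted p = 0.524 with an estimated correlation). Besides Vwf, Tie1 fell 36.7-fold and Mmrn2 30.5-fold in the authors' deposited table. All 27 macrophage and leukocyte markers in the table, of 32 fixed, fell, with 27 called adjusted over the list alone (Fisher's exact test, adjusted p = 2.96e-04, and adjusted p = 0.524 with an estimated correlation). Itgam fell 14.7-fold, the platelet factor gene Pf4 9.98-fold and Fcer1g 9.46-fold in the authors' deposited table.

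The 14 peritubular myoid markers in the table, of 23 fixed, and the 14 interstitial fibroblast markers, of 29 fixed, fell, with 14 called in each adjusted over the list alone (Fisher's exact test, adjusted p = 0.0165 for each, and adjusted p = 0.524 with an estimated correlation). Mcam fell 8.21-fold, the smooth muscle myosin gene Myh11 4.26-fold and Casq2 3.94-fold in the authors' deposited table. Among fibroblast markers, Ly6a fell 7.70-fold, Ogn 4.36-fold and Dpep1 3.95-fold in the authors' deposited table. Without genes that another list also held, the adjusted p was 0.0699 for the myoid and 0.174 for the fibroblast list. Of 22 Leydig cell markers, 9 were in the table, with 4 higher and 5 lower and 9 called adjusted over the list alone (Fisher's exact test, adjusted p = 0.573). Hsd3b1, an enzyme of steroid synthesis, rose 5.0-fold and Jam2 fell 4.77-fold in the authors' deposited table.

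**Figure D3:**
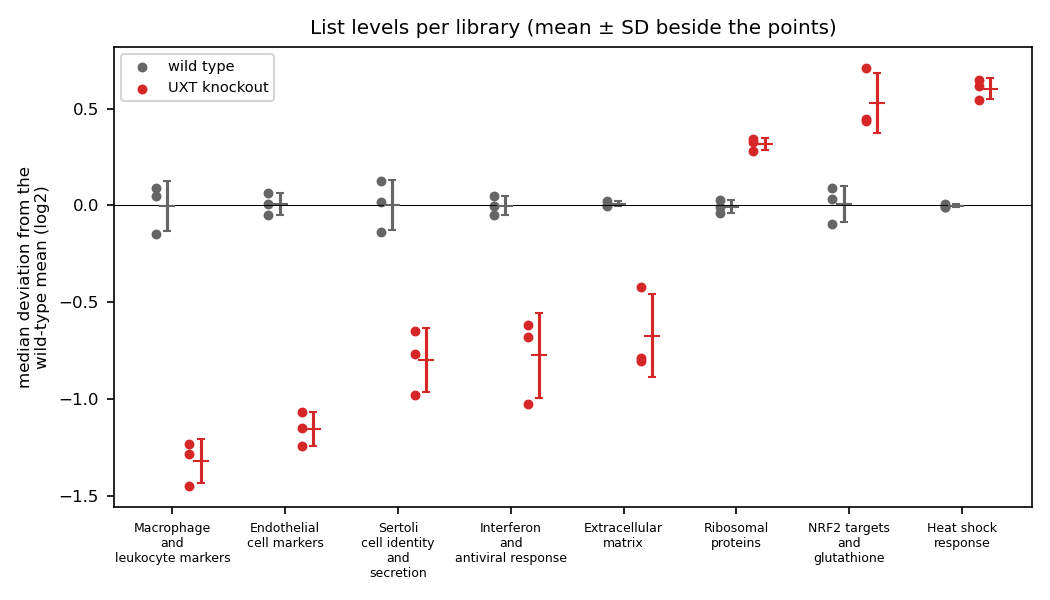
Points are libraries (grey wild type, red knockout; 3 each), and the y axis is the median deviation of a list's genes from the wild-type mean on the log2 scale, with mean ± SD bars beside the points. Knockout means run from -1.32 for macrophage markers to 0.60 for heat shock genes, and the groups do not overlap in any list shown. The values are moderated, so sizes cannot be compared between lists.

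Too few genes of the other lists were called to test their balance. Of 61 cell cycle genes, 3 were in the table and called, as adjusted over the list alone, with Ccnd1 1.88-fold higher and Anln 1.66-fold lower in the authors' deposited table. Of 49 respiratory chain genes, 1 was in the table, the muscle isoform gene Cox7a1, which fell. Of 37 chromatin repressor and germline genes, 4 were in the table and 3 were called, with Trim28 1.57-fold higher in the authors' deposited table. Of 38 male germ cell markers, 4 were in the table, with 1 higher and 3 lower. Kit fell 4.19-fold and Uchl1 rose 1.57-fold in the authors' deposited table. Of 12 red blood cell markers, 1 was in the table, the heme synthesis gene Alas2, which fell.

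With only genes of at least a fold of 2 in the authors' deposited table, 302 genes were higher and 1438 lower, and 4 of the 16 called lists passed, namely interferon, heat shock, NRF2 and macrophage genes. With a fold of 1.5 on the moderated scale of the deposited values per library, an alternative added after seeing the data, 218 genes were higher and 956 lower and 3 lists passed. The macrophage list was lost there (Fisher's exact test, adjusted p = 0.0651).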

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

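The fold threshold on the scale of the deposited values, the removal of cell type markers and the comparison with called genes in none of the lists were chosen after the data were seen. DESeq2, edgeR on counts or recovered reads, size factors and pseudocounts of 0.5 and 5 were not run, since the values were already on a log2 scale without counts. The alternatives for the level of Uxt were not run, since Uxt was not analysed here. Without counts, what depth limits could not be assessed.

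Quantile normalization left 1143 lower genes in place of 2200, and the cause was not tested. It forces equal distributions on a table selected with mostly lower genes. It turned the difference of Tm7sf2 from -0.37 to 0.048, and ended the calls of Rhox5 (-0.07) and Perp (-0.19). A fold of 2 left 302 higher and 1438 lower genes and 4 lists with a called direction in place of 16. A fold of 1.5 on the moderated scale left 218 higher and 956 lower genes and 3 lists. Fewer genes entered these tests. Of the called genes, 82.6% were lower at a fold of 2 and 81.4% on the moderated scale, against 67.8% in the main test. A list of lower genes can then differ less from the other called genes. Without cell type markers 10 lists passed, with 4 of the 6 lost lists emptied by that removal. Without genes that another list also held 12 lists passed, with the junction, actin, myoid and fibroblast lists lost. With camera and a preset correlation the 16 lists passed, with an estimated correlation 0 passed, and fry called 23, which the selection of the table favours. The camera runs differed in how the correlation was set and in the degrees of freedom, which are few when the correlation is estimated. The camera adjusted p = 0.524 therefore does not measure the correlation between genes alone. For ribosomal proteins the estimate was negative, yet the camera adjusted p went from 0.011 to 0.524. The estimates for the 16 lists ran from -0.05 for ribosomal proteins to 0.54 for NRF2 targets.

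Leaving out each library in turn gave 1014 to 1034 higher genes, 2085 to 2158 lower genes and 15 to 16 lists. The loss came without wild-type replicate 1 (NF-kB list). With the replicate number as a block, 1045 genes were higher and 2207 lower and 16 lists passed. The values gave no sign that the numbers pair the libraries. The deviations of same-numbered libraries correlated at 0.18, -0.07 and -0.004, and 2 of 6 libraries correlated best with their own number. With 3 libraries per group and selected genes, this cannot exclude a pairing. An adjusted p of 0.01 gave 943 higher and 1938 lower genes and 15 lists, with the actin list lost, the ribosomal list left with too few genes to test and the TGF-beta list gained (0.0323), and a minimum mean of 50 gave 994, 1836 and 16. The named genes kept direction and side of the threshold in 735 of their alternative values, with 2 weaker and 1 reversed. Where a list could be tested by Fisher's exact test, it did so in 375, with 29 weaker, 1 stronger and 0 reversed. That tally leaves out the 16 lists lost under camera, the prefoldin and ribosomal lists, which had too few genes at either stricter fold, and the 4 emptied marker lists. It also leaves out the ribosomal list at an adjusted p of 0.01, where too few genes were left.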

Other observations

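The tests of cell loss, of interferon transcripts carried by macrophages, of the viral construct and of a shared factor were chosen only after the result was seen, as were the checks of single families and of the X chromosome and chromosome 13 that follow their overall tests.

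Host genes of small nucleolar RNAs rose together. All 9 called genes with symbols starting in Snhg were higher, of 28 symbol families tested (Fisher's exact test, adjusted p = 3.38e-04). In the authors' deposited table Snhg7 was 5.88-fold, Snhg1 3.57-fold and the related host gene Gas5 3.07-fold higher. In total 6 families passed. Only called genes of the selected table were counted, so the rest of each family is unknown. The Rpl and Col families share genes with the ribosomal and matrix lists. Fisher's exact test takes genes as independent, and no test with an estimated correlation was run on families or chromosomes. Zinc finger genes named Zfp were mostly higher (45 higher, 8 lower; adjusted p = 4.85e-14), as were Wdr genes (11 and 2; adjusted p = 0.00101) and Polr genes of the RNA polymerases (9 and 1; adjusted p = 0.00144). The 11 called Rpl genes, whose values are uncertain because of pseudogenes, were higher (adjusted p = 5.18e-05) and the 20 called Col collagen genes lower (adjusted p = 0.0024). These directions also passed after quantile normalization, where 45 Zfp genes were higher and 1 lower and the semaphorin genes passed too, with 10 lower and 0 higher. With all libraries as deposited, 13 semaphorin genes were lower and 0 higher (adjusted p = 0.0522).

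Genes of the X chromosome, which also carries Uxt, were more often lower than those of other chromosomes. Of 120 called X genes, 18 were higher and 102 lower, or 85.0% lower (Fisher's exact test over 20 chromosomes, adjusted p = 3.15e-04). Among 10000 random sets matched on expression the median was 70.0% lower and the highest 85.8% (permutation p = 0.0002). Outside the fixed lists and the Zfp genes the counts were 17 and 89 (adjusted p = 0.00122), and after quantile normalization 18 and 55 (adjusted p = 8.40e-04). With a fold of 2 in the authors' deposited table they were 7 and 72 (adjusted p = 0.306), so the balance then did not pass. At that fold 82.6% of all called genes were lower, which leaves less room for a difference. Chromosome 13 differed the other way, with 54 higher and 54 lower (adjusted p = 9.40e-04). Outside the lists and the Zfp genes chromosome 13 had an adjusted p = 6.51e-04. Both the Fisher tests and the random sets take the genes of a chromosome as independent. The cause was not tested further for either chromosome.

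Endothelial and macrophage markers were lower in the knockout. Against larger folds of weakly expressed genes as the whole cause, none of 10000 random lists matched on expression had a median as low as the -2.47 of the 49 joined markers in the authors' deposited table (permutation p = 0.0001, the smallest these lists can give; lowest median -1.50). Fewer endothelial cells and macrophages in the knockout cultures stay open, since the absence of higher members and medians of -3.25 and -2.37 in the authors' deposited table restate the pattern, and lower transcription within those cells would give them too. The abundant macrophage gene Lyz2 fell from 14.45 ± 0.19 to 12.82 ± 0.12 and the endothelial gene Cdh5 from 12.04 ± 0.06 to 11.52 ± 0.19 (SD, n = 3 each). In the authors' deposited table Cdh5 fell 1.73-fold and Vwf 51.8-fold. The SD of the members' log2 fold changes there was 1.61 for endothelial and 0.64 for macrophage markers. Such unequal falls do not decide the question, since markers that the remaining cells also express would fall less.

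Interferon genes were lower in the knockout. A loss of interferon transcripts carried by macrophages stays open, because the median fall was smaller than that of macrophage markers by 1.10 on the log2 scale in the authors' deposited table, with 0 genes shared by the lists. Within groups, the libraries had the same order by both lists in 1 of the 2 groups. A milder fall is what such a loss could give, but also what a separate change in the Sertoli cells could give. The viral construct with Cre also cannot be told apart from the loss of UXT, since 0 libraries had Cre with an intact gene or the knockout without Cre.

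All 15 heat shock genes and 13 of 18 NRF2 genes in the table were higher in the knockout, with an adjusted p = 0.524 for each list with an estimated correlation. An equal factor for all genes of the remaining cells would give equal rises. Against such a factor as the whole cause, the heat shock genes' log2 fold changes ran from 0.68 to 2.13 in the authors' deposited table. Their spread was 2.98 times the median SE of limma once each SE was rescaled from the moderated values to that fold change. Unequal factors, as where lost cells also held some of these transcripts, stay open. Against gene length or GC content as the whole cause, their trend held 1.52% of the variance of the table's log2 fold changes, and the median of the 33 joined genes was 1.64 after it was removed, against 0.87 before (the trend carries the table's own median of -0.88), with a 95th percentile of 0.08 for random lists. A response to the viral construct with Cre, or to the loss of UXT, may remain, and the 0 libraries that would separate them keep this open.

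Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, the real split called 3244 genes with limma and the highest of the others called 0. The real split was 1 of the 10 to call as many, and the table had been selected on it.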
